A study of Mus musculus with 8 samples.

How the data were processed

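Gene expression was measured in the hippocampus of 8 SCID mice, 4 treated with FTY720 and 4 with saline, with 1 Affymetrix 3' array per mouse hybridised with biotin-labelled RNA made from 100 ng of total RNA, per the labels. The deposited table holds log2 values per probe set, a scale read from the values themselves, whose range and near-equal array distributions are like those that RMA gives. Affymetrix Expression Console, MAS5 and RMA are named in the submitters' processing notes without versions or roles, so which of them made these values is not given in the sources used here. Probe set summaries of this kind shrink small signals toward the background, so differences of dim genes are understated. No genome build, slide or scan date is given in the sources used here, so no coordinates are printed and no batch could be tested.

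Of the 22690 probe sets, 20380 had 1 gene symbol in the platform annotation, 691 had several and 1619 had none, the latter with the 64 control probe sets. By Entrez ID, 20364 of those with 1 symbol were found in the RefSeq gene table, which was used for names only, and no symbol changed. Each gene was represented by the probe set of highest mean log2 value among those annotated to that gene alone, which gave 12393 genes, 4956 of them with more than 1 probe set. No gene was removed for low signal and no pair of arrays was identical. The values were used as deposited, with no further normalization and no pseudocount.

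FTY720 was compared with vehicle with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, no covariate, all 8 arrays), with Benjamini-Hochberg adjustment over all genes. The replicate numbers differ between the groups, so no pairing applies. SE values are those of the moderated fit, SD values are between mice. For 36 gene lists with at least 5 measured members, camera with a preset correlation of 0.01 compared the list with all other genes, with adjustment over the lists. Beside it stand camera with the correlation estimated from the data, fry, which tests a list on its own, and a two-sided exact permutation test over the 70 assignments of the mice to the groups, whose smallest p is 0.0286. List members were also adjusted over the list alone. Some genes belong to several lists. The test, the lists, the rule for named genes and most alternatives were chosen before the data were examined.

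Genes were named by a fixed rule, which in its first step passed over predicted-gene and clone names. Among genes with a mean level above the median of all genes, those past an adjusted p of 0.05 would have been named by size, 12 per direction. As none passed, the 12 per direction of smallest unadjusted p whose FTY720 and vehicle values did not overlap were named. Added to these were the 3 members of each list with the smallest unadjusted p, and in every case S1pr1 to S1pr5, Sphk1, Sphk2, Hdac1, Hdac2, Hdac3, Hdac8, Fos, Egr1, Arc, Npas4, Bdnf and Nr4a1. S1pr2, Hdac8 and Npas4 had no probe set annotated to them alone and were not tested. Further list members, chosen after their values were seen, are named as examples. In the Results these are Mbp, Mobp, Fa2h, Cldn11, Cnp, Sox10, Olig1, Plin4, Mertk, Sgk1 and Per1. The later sections add Egr2, Dusp1, Junb, Kcne2, Sostdc1, Otx2 and Tac1.

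The fit and camera were checked on simulated data with independent noise around the real gene means, with 200 of 12393 genes changed. The 200 were drawn from genes above the median level. The fit recovered 66%, 98%, 100% and 100% of genes changed 1.25-fold, 1.5-fold, 2-fold and 3-fold, and 12 of its 194 calls were unchanged genes. The oligodendrocyte and myelin list was also lowered as a whole in that noise, and camera called it and no other list. As the simulated genes varied independently, this does not test camera on lists whose genes vary together. Array quality was described by the correlation between arrays, principal components, the 18S control level and the 5' minus 3' differences of the actin and Gapdh control probe sets.

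Alternatives covered quantile normalization, centring on brighter genes, filters on dim genes, other ways to choose probe sets, trended, robust and array-weighted variance models, a minimum fold of 1.1 and leaving out each mouse in turn. After the data were seen, 3 were added, which left out vehicle 15 and 16 together or used the Gapdh 5' minus 3' difference or the choroid plexus list mean as a covariate. All 35 splits of the 8 mice into 4 and 4, counting mirror images once, were fitted for comparison.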

Results

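Hippocampal RNA was profiled in 8 male SCID mice aged 12 weeks, a strain that lacks mature B and T lymphocytes. The mice went through contextual fear conditioning, and 4 of them received FTY720 by mouth at 1 mg/kg on 3 days while 4 received saline. FTY720 (fingolimod) is a sphingosine analogue that is phosphorylated in tissue and then acts on sphingosine-1-phosphate receptors. Tissue was taken 1 hour after the consolidation test and 17 hours after the last dose. Each mouse gave 1 Affymetrix 3' expression array, so all differences below are between separate animals (n = 4 per group). Mice are named by treatment and replicate number, 1, 4, 5 and 6 for FTY720 and 13 to 16 for vehicle. After annotation, 12393 genes were tested, with a median level of 7.17 on the log2 scale and a median standard error (SE) of 0.07 for the difference between the groups. The number of mice limits this precision.

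The arrays resembled each other closely, with array medians between 6.68 and 6.72. Vehicle 15 had the lowest median correlation with the other arrays, 0.994, and lay alone on the first principal component, which held 35.7% of the variance. Vehicle 16 lay alone on the second component (19.6%) and had the steepest loss of 5' signal. Its 5' minus 3' difference was -1.46 for the Gapdh control probe sets and -2.74 for those of actin. Group means of the Gapdh difference were -0.95 ± 0.14 (SD) in FTY720 mice and -1.20 ± 0.18 in vehicle mice (n = 4 each, two-sided exact permutation p = 0.0571). For actin they were -2.34 ± 0.11 and -2.54 ± 0.14 (n = 4 each, exact permutation p = 0.0571).

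The comparison of FTY720 with vehicle addressed which hippocampal transcripts differ with the drug after a fear memory test. Oligodendrocyte and myelin genes, the list of smallest camera p, fell by 0.30 on the log2 scale on average, with all 20 measured members on the lower side. Glucocorticoid-responsive genes rose by a mean of 0.12, with Fkbp5 at 0.35 and Tsc22d3 at 0.30. Lists of thalamus, striatum, choroid plexus and cytosolic ribosomal genes were also lower, and vehicle 15 had the highest means of the first 3. All 6 of these calls were lost with an estimated correlation (adjusted p = 0.872, and 0.880 for choroid plexus). Among single genes, none of which passed adjustment, Crym and Npr3 led those with higher and Ugt8a and Erbin those with lower values in FTY720 mice. Sphingosine-1-phosphate receptors with sphingolipid enzymes, histone deacetylases with their complexes, and immediate early genes did not pass as lists.

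No gene passed an adjusted p of 0.05 in the limma fit over all genes, where the lowest adjusted p was 0.536. At an unadjusted p under 0.05 there were 823 genes, 478 higher and 345 lower in FTY720 mice, where chance gives 619.7. At an unadjusted p under 0.01 there were 172, 98 higher and 74 lower, where chance gives 123.9. In 557 genes (4.49%) the values of the groups did not overlap, against 2.86% by chance. Only 37 genes differed by 1.5-fold or more, and 18 of these had an unadjusted p under 0.05. On simulated data with independent noise, 98% of genes changed 1.5-fold and 100% of those changed 2-fold were recovered. The changed genes were drawn from those above the median level. That noise lacked differences shared between genes, so the simulation does not show that real changes of this size would pass here. The count of 172 was 110 without FTY720 6 and 74 when the Gapdh 5' minus 3' difference was a covariate. That covariate was itself uneven between the groups, with means of -0.95 in FTY720 and -1.20 in vehicle mice. It therefore takes up part of any treatment difference too, and the fall to 74 does not show an effect of RNA integrity.

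Among genes above the median level, the 12 of smallest unadjusted p with higher values in all 4 FTY720 mice were led by Crym, a thyroid hormone-binding protein, at 10.78 ± 0.09 (SD) against 10.31 ± 0.10. Its log2 difference was 0.47 (SE 0.07, limma adjusted p = 0.536). Dcn, the extracellular proteoglycan decorin, had the largest difference of the 12, 0.90 (SE 0.19), or 1.86-fold. Npr3, the clearance receptor for natriuretic peptides, differed by 0.66 (SE 0.11) and the cation channel gene Trpc4 by 0.39 (SE 0.06). Kcnn2, a calcium-activated potassium channel, differed by 0.38 (SE 0.07) and Pde1a, a calmodulin-dependent phosphodiesterase, by 0.35 (SE 0.08). The others were Nabp1 (0.44), Parm1 (0.43), Fgf11 (0.35), the ephrin gene Efna3 (0.29), Tmtc4 (0.26) and Sec24d (0.25), a coat component of transport vesicles. Without vehicle 15 and 16, arrays doubted after the data were seen, the differences of Dcn, Nabp1 and Tmtc4 were 0.58, 0.29 and 0.17. With all probe sets of a gene averaged, that of Fgf11 was 0.16, where the other probe set was dimmer, at a mean level of 4.94 against 7.41.

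Values were lower in all 4 FTY720 mice than in every vehicle mouse in 220 genes. Named here are the 12 of smallest unadjusted p among those above the median level. Of these 12, Ugt8a, the galactosyltransferase that makes the myelin lipid galactosylceramide, had a log2 difference of -0.52 (SE 0.10, limma adjusted p = 0.634). Mog, a myelin surface glycoprotein, stood at -0.54 (SE 0.12), Evi2a at -0.45 (SE 0.11) and Aspa, the oligodendrocyte enzyme that cleaves N-acetylaspartate, at -0.44 (SE 0.10). Erbin, a scaffold protein that binds an ErbB receptor, differed by -0.41 (SE 0.08) and Septin4 by -0.37 (SE 0.09). Slain1 (-0.33), Pkig (-0.30), Il1rap (-0.28), Fgfr2 (-0.28), Pmp22 (-0.26) and Reep3 (-0.24) completed the group. The sign was shared by 1 of 3 probe sets for Slain1, 1 of 2 for Fgfr2 and 2 of 3 for Il1rap. Without probe sets prone to cross-hybridisation Fgfr2 stood at 0.03 and Pkig at -0.10. The other probe set of Fgfr2 was dimmer, at a mean level of 5.38 against 8.71. The disagreeing one of Il1rap was at 3.97 against 7.26. With all probe sets of a gene averaged, Fgfr2, Il1rap, Reep3 and Slain1 stood at -0.13, -0.13, -0.11 and -0.09. Without vehicle 15 and 16, Erbin stood at -0.26 and Slain1 at -0.20, and with the Gapdh 5' minus 3' difference as a covariate Ugt8a stood at -0.32 and Mog at -0.31.

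**Figure D1:**
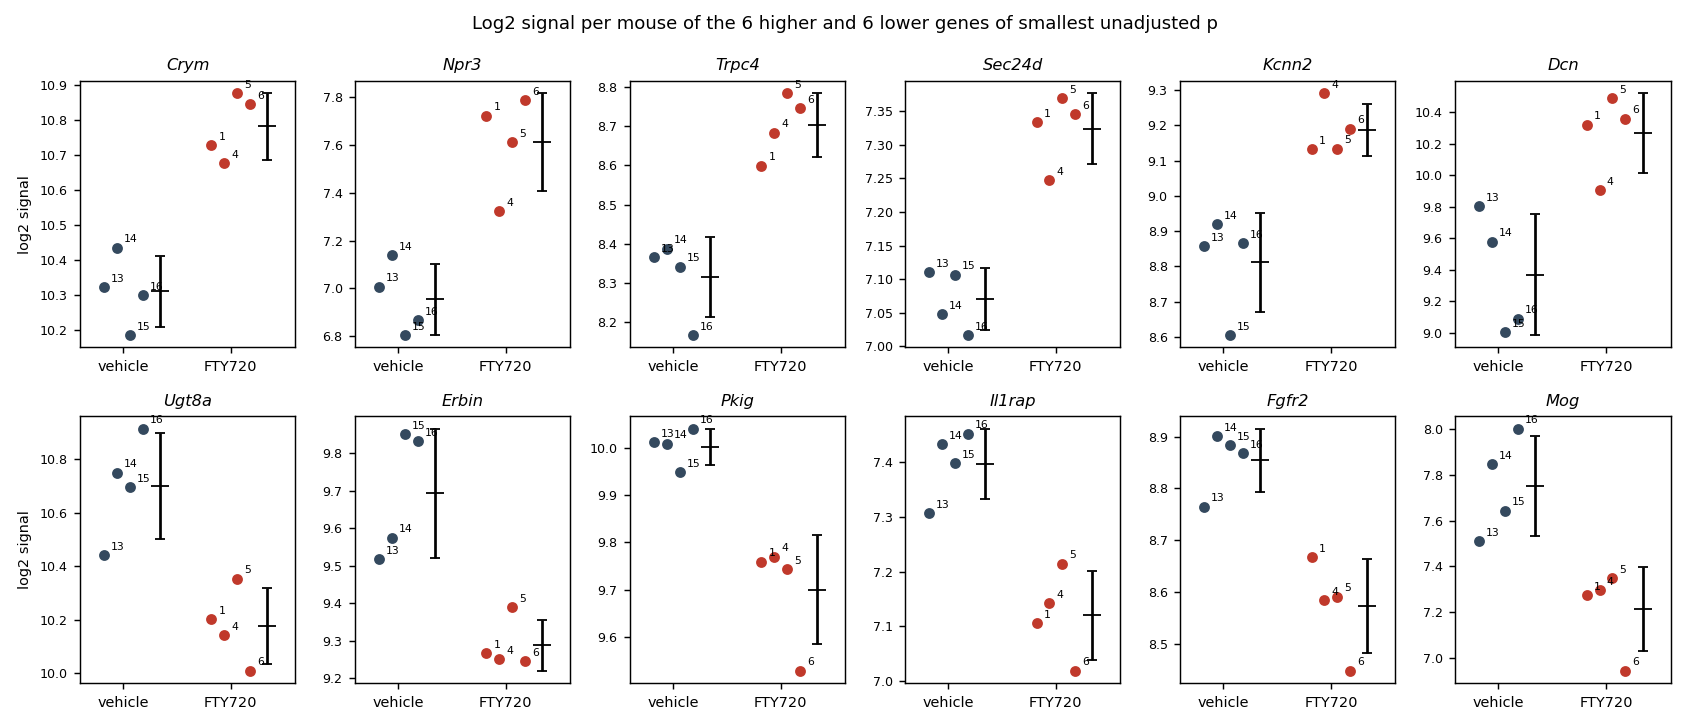
Log2 signal (vertical axis) of 12 genes in each mouse, vehicle in dark blue and FTY720 in red, with replicate numbers beside the points and bars giving the mean ± SD of 4 mice. Only genes above the median level whose group values do not overlap were eligible. Of these, the upper row holds the 6 of smallest unadjusted p that were higher in FTY720 mice and the lower row the 6 that were lower.

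The oligodendrocyte and myelin list fell by 0.30 on the log2 scale on average (limma camera with a preset correlation of 0.01, adjusted p = 9.0e-21). Its genes moved together from mouse to mouse, with an estimated correlation of 0.71, and camera with that estimate gave p = 0.0315, adjusted p = 0.872. All 20 measured members were lower in FTY720 mice, 15 of them at an unadjusted p under 0.05, and none passed over all genes while 15 passed when adjusted over the list alone. The members covered compact myelin proteins, with Mbp at -0.16 (SE 0.06) and Mobp at -0.31 (SE 0.11), and myelin lipid enzymes, with Fa2h at -0.30 (SE 0.08). Cldn11, the tight junction protein of myelin, differed by -0.48 (SE 0.13), Cnp by -0.33 (SE 0.10) and Ppp1r14a by -0.45 (SE 0.11). The transcription factors of the lineage had the smallest differences, -0.15 (SE 0.06) for Sox10, -0.11 (SE 0.06) for Olig2 and -0.08 (SE 0.07) for Olig1. Per mouse, the list mean lay between -0.26 and -0.07 in FTY720 mice and between -0.05 and 0.30 in vehicle mice, relative to the mean of all 8. The exact permutation p of 0.0286 was the smallest that 4 against 4 mice allow, with an adjusted p of 0.823 over the 36 lists. The value was -0.17 with the Gapdh 5' minus 3' difference as a covariate, and that difference was lowest in vehicle 16, the mouse with the highest list mean. Precursor markers of the lineage did not pass (9 genes, mean -0.03, camera adjusted p = 0.606), with Matn4 at 0.15 and Cspg5 at -0.16, and Olig2 counted here too.

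**Figure D2:**
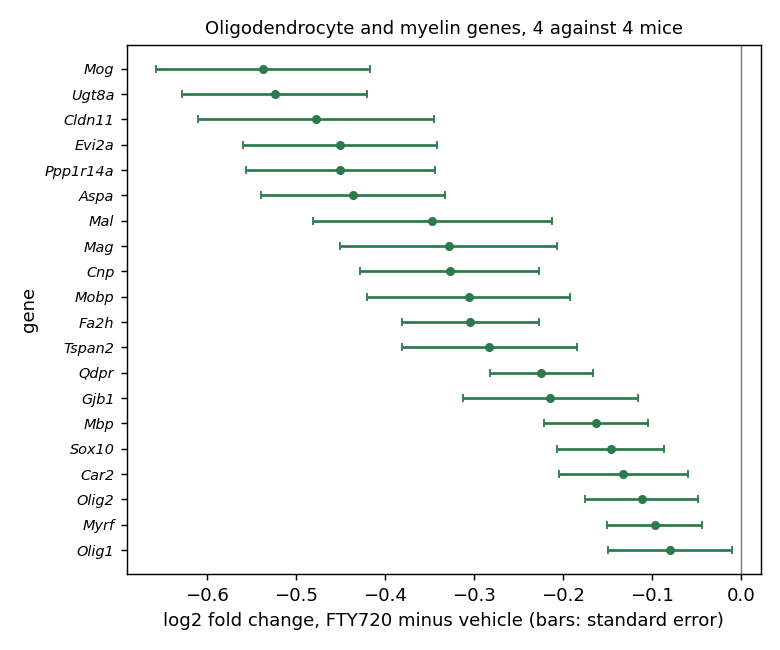
Log2 fold change (horizontal axis, FTY720 minus vehicle, bars ± SE of the limma fit, 4 mice per group) of the 20 measured oligodendrocyte and myelin genes. All lie below 0, from -0.54 for Mog to -0.08 for Olig1.

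Glucocorticoid-responsive genes rose by a mean of 0.12 (19 genes, camera adjusted p = 2.27e-03), with 14 higher and 5 lower. With an estimated correlation the list's adjusted p = 0.872. None passed over all genes and 5 passed when adjusted over the list alone. These were Fkbp5, a co-chaperone of the glucocorticoid receptor, at 0.35 (SE 0.09), Tsc22d3, which encodes the glucocorticoid-induced leucine zipper, at 0.30 (SE 0.08), Sult1a1 at 0.43 (SE 0.12), Plin4 at 0.37 (SE 0.11) and Mertk at 0.28 (SE 0.08). Sgk1 (-0.09) and Per1 (-0.11), also known targets of the receptor, had values on the other side of 0. Without FTY720 4 the list mean was 0.09 (camera adjusted p = 0.0652). Vehicle 15 had the lowest list mean of the 8 mice, -0.17.

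Heat shock and chaperone genes did not pass (18 genes, mean 0.07, camera adjusted p = 0.0609). Their leading members were Hspa1a at 0.27 (SE 0.07), the co-chaperone Bag3 at 0.24 (SE 0.07) and Hspb1 at 0.16 (SE 0.05), with Hspa1b at 0.36 (SE 0.13), and 12 of the 18 were higher. This list passed in 7 of 19 alternative settings, among them the fit without vehicle 15 (adjusted p = 8.72e-03). Unfolded protein response genes stood at a mean of 0.02 (21 genes, adjusted p = 0.606), with Hspa5 at 0.16, Calr at 0.11 and Creld2 at -0.11.

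The receptors of FTY720 were tested as RNA, within a wider list that also holds sphingolipid enzymes, and that list did not pass. Sphingosine-1-phosphate receptors and sphingolipid enzymes had a mean of -0.02 (29 genes, camera adjusted p = 0.754), 16 higher and 13 lower. S1pr1 differed by 0.08 (SE 0.08), S1pr3 by 0.05 (SE 0.08) and S1pr4 by -0.04 (SE 0.07). S1pr5, the receptor typical of oligodendrocytes, differed by -0.41 (SE 0.13, limma adjusted p = 0.719). The kinases Sphk1 and Sphk2, which phosphorylate the drug, stood at 0.13 (SE 0.10) and -0.11 (SE 0.13). The other probe set of Sphk2 gave 0.14 (SE 0.07), Sphk2 stood at 0.04 without vehicle 16, and Sphk1 stood at 0.05 without vehicle 15. Of this list, 1 gene passed when adjusted over the list alone, Ugt8a, which also belongs to the myelin list, and Cers2, a ceramide synthase, stood at -0.20 (SE 0.07). S1pr2 was not tested because no probe set was annotated to it alone.

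Histone deacetylases and their complexes had a mean of -0.03 (21 genes, camera adjusted p = 0.175) and no member at an unadjusted p under 0.05. This list is wider than the class I deacetylases, the proposed nuclear targets of phosphorylated FTY720. The arrays measure the RNA of these enzymes and not their activity, so the values do not test whether the drug inhibits them. Hdac1 differed by 0.03 (SE 0.04), Hdac2 by -0.17 (SE 0.12) and Hdac3 by 0.07 (SE 0.05), and Hdac8 was not tested. Without vehicle 15 Hdac2 stood at -0.06 and Hdac3 at 0.04, and without vehicle 14 Hdac2 stood at -0.28. The lowest p in the list belonged to Mta1 (-0.11), Chd4 (-0.08) and Rcor1 (-0.07). Histone acetyltransferases did not pass (11 genes, mean 0.01, adjusted p = 0.841), with Kat2b at -0.25 (SE 0.08), Ncoa1 at 0.14 and Kat6a at 0.08. Genes known as induced by deacetylase inhibitors had a mean of 0.06 (15 genes, adjusted p = 0.649), with Ccn2 at 0.36 beside Hspa1b and Tsc22d3. Without vehicle 15 the list mean was -0.007 and Ccn2 stood at 0.20. Core and linker histone genes stood at -0.01 (16 genes, adjusted p = 0.631), with H2az1 at -0.11, H1f4 at -0.12 and H2aw at 0.11.

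Activity-regulated immediate early genes, which neurons induce within an hour of a learning test, had a mean of -0.05 (39 genes, camera adjusted p = 0.316), 17 higher and 22 lower. Fos was 8.69 ± 0.45 (SD) in FTY720 mice and 9.10 ± 0.69 in vehicle mice, a difference of -0.41 (SE 0.33). Egr1 differed by -0.31 (SE 0.24), Nr4a1 by -0.12 (SE 0.23), Arc by -0.08 (SE 0.43) and Bdnf by 0.05 (SE 0.17), and Npas4 was not tested. The smallest p values were those of Nptx2 at -0.36 (SE 0.14), Jun at 0.29 (SE 0.13) and Nr4a2 at 0.40 (SE 0.21). Vehicle 16 carried the highest list mean, 0.39, with the other mice between -0.19 and 0.07. The list mean was 0.07 without vehicle 16 and -0.12 without vehicle 15, where it passed as lower by camera with the preset correlation. Without vehicle 16, the mouse with the steepest loss of 5' signal, Fos differed by -0.07, Egr1 by -0.03, Nr4a1 by 0.13, Arc by 0.37 and Nptx2 by -0.21. Without vehicle 15 Bdnf stood at -0.15, Jun at 0.18 and Nr4a2 at 0.20.

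Synaptic plasticity and memory genes had a mean of 0.05 (36 genes, 27 higher, camera adjusted p = 0.0848), with Reln at 0.33 (SE 0.14), Syn2 at 0.23 (SE 0.10) and the glutamate receptor gene Gria1 at 0.21 (SE 0.10). The list mean was 0.016 without vehicle 15, and without vehicle 16 Reln stood at 0.22, Syn2 at 0.15 and Gria1 at 0.13. GABA receptor and synapse genes did not pass (13 genes, adjusted p = 0.960), with a mean of -0.05, or 0.014 without vehicle 15. Among them Gabrd, the delta subunit found outside synapses, stood at -0.60 (SE 0.19), or -0.43 without vehicle 16. Gabrb1 stood at 0.18 and Gabra2 at 0.12. Neuropeptides and their receptors had a mean of -0.07 but a median of 0.02 (35 genes, adjusted p = 0.960), and a mean of 0.0012 without vehicle 15. Gastrin-releasing peptide, Grp, stood at 0.80 (SE 0.21), or 0.57 without vehicle 15, Npy2r at 0.24 (SE 0.08) and Vipr2 at -0.20 (SE 0.06). Neurotrophic factors and their receptors stood at 0.01 (19 genes, adjusted p = 0.960), with Ret at -0.13, Gdnf at -0.26 and Lif at 0.09. Ret, Gdnf and Lif had mean levels below the median of all genes, that of Gdnf 3.79.

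Lists for brain regions next to the hippocampus were uneven between mice. Thalamus and habenula markers fell by a mean of 0.53 (18 genes, 16 lower, camera adjusted p = 1.16e-06, and 0.872 with an estimated correlation), led by Tcf7l2 at -1.44 (SE 0.51), Tnnt1 at -0.98 (SE 0.35) and Ramp3 at -0.74 (SE 0.24). Striatum markers fell by a mean of 0.52 (11 genes, 10 lower, camera adjusted p = 1.95e-04, and 0.872 with an estimated correlation), with enkephalin, Penk, at -1.14 (SE 0.53), Rasd2 at -0.41 (SE 0.19) and Rarb at -0.70 (SE 0.37). Vehicle 15 had list means of 1.23 for thalamus and 1.31 for striatum, where the highest other mouse stood at 0.18 and 0.29. Without vehicle 15 the means were -0.21 and -0.17, and without vehicle 15 and 16 they were -0.35 and 0.03. The named genes without vehicle 15 were Tcf7l2 at -0.87, Tnnt1 at -0.57, Ramp3 at -0.51, Penk at -0.61, Rasd2 at -0.19 and Rarb at -0.26. With the preset correlation both lists passed whichever single mouse was left out. Neocortex markers did not pass (16 genes, mean -0.04, adjusted p = 0.274), with Fezf2 at 0.65 (SE 0.26), Krt12 at -0.49 (SE 0.20) and Lamp5 at -0.49 (SE 0.23), and vehicle 16 had the highest list mean, 0.30. The neocortex mean was 0.055 without vehicle 16 and -0.11 without vehicle 15. Fezf2 stood at 0.33 without vehicle 15 and Lamp5 at -0.21 without vehicle 16.

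Choroid plexus and ependymal markers fell by a mean of 0.40 (15 genes, all lower, camera adjusted p = 0.0436), but their SD between mice was 1.00 in FTY720 and 0.93 in vehicle mice. With an estimated correlation the adjusted p = 0.880. Ttr, the transthyretin of the choroid plexus, was 13.16 ± 1.33 (SD) and 13.85 ± 0.71, Folr1 differed by -0.78 (SE 0.48) and Rarres2 by -0.19 (SE 0.17). The call was lost without FTY720 4, FTY720 6, vehicle 14 or vehicle 15, and the mean ranged from -0.72 without FTY720 1 to -0.05 without vehicle 15.

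**Figure D3:**
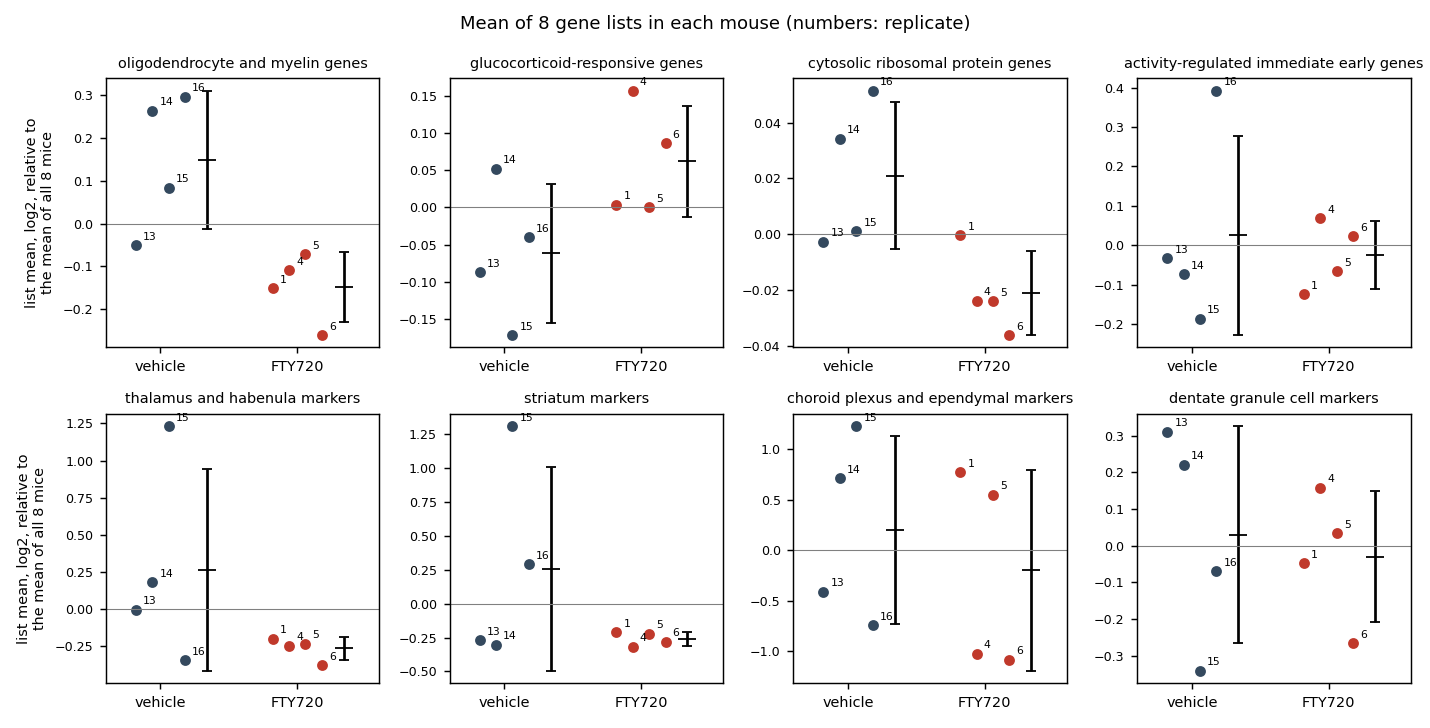
Mean of 8 gene lists in each mouse (vertical axis, log2, relative to the mean of all 8 mice), vehicle in dark blue and FTY720 in red, with replicate numbers beside the points and bars giving the mean ± SD of 4 mice. Oligodendrocyte and myelin genes separate the groups, vehicle 15 stands apart at 1.23 for thalamus and 1.31 for striatum, and choroid plexus varies from -1.09 to 1.23 across both groups.

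Marker lists of hippocampal neuron types did not pass with all 8 mice. Interneuron markers had a mean of 0.04 (20 genes, camera adjusted p = 0.175), and 3 passed when adjusted over the list alone. These were the serotonin receptor gene Htr3a at 0.25 (SE 0.05), the cannabinoid receptor gene Cnr1 at 0.44 (SE 0.09) and Lhx6, a transcription factor of interneurons, at 0.23 (SE 0.06). Markers of Ammon's horn pyramidal cells had a mean of -0.01, a median of 0.01 and an upward camera direction (13 genes, adjusted p = 0.821). In that list 3 genes passed when adjusted over the list alone, Dcn and Ccn3 at 0.48 (SE 0.12) on one side and Pcp4 at -0.57 (SE 0.18) on the other, which was -0.36 without vehicle 15. Dentate granule cell markers stood at -0.06 (11 genes, adjusted p = 0.205), with Il1rap passing when adjusted over the list alone, Prox1 at 0.18 and Maml2 at -0.15. Their list mean was lowest in vehicle 15, -0.34, and the difference was -0.18 without that mouse (camera with the preset correlation, adjusted p = 9.44e-04). Camera with an estimated correlation was run on all 8 mice only, where the dentate estimate was 0.44 and the adjusted p = 0.880. Genes of adult neurogenesis and proliferation did not pass (20 genes, mean -0.05, adjusted p = 0.212), with Cdk1 at -0.30 (SE 0.10), Sox4 at -0.19 and Top2a at -0.22. The mean ranged from -0.089 without vehicle 16 to -0.017 without vehicle 15, Cdk1 stood at -0.19 without vehicle 14 and Top2a at -0.14 without FTY720 6.

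Among glia and vessels, astrocyte markers stood at -0.01 (19 genes, camera adjusted p = 0.628), with the water channel Aqp4 at -0.23 (SE 0.07), Fgfr3 at 0.14 (SE 0.06) and Gjb6 at 0.19 (SE 0.08). Microglia and macrophage markers had a mean of -0.04 (23 genes, adjusted p = 0.121). Gpr34, a microglial receptor, stood at -0.33 (SE 0.07) and passed when adjusted over the list alone, while Ctss (-0.15) and Aif1 (-0.17) did not. Without vehicle 15 the microglia mean was -0.08 (adjusted p = 9.44e-04), and with the Gapdh 5' minus 3' difference as a covariate it was 0.04. Endothelial markers had a mean of -0.05 (21 genes, adjusted p = 0.165), with Ctla2a at -0.26, Abcb1a at 0.15 and Cldn5 at -0.21, and the covariate gave 0.01. The mean ranged from -0.079 without vehicle 15 to -0.0093 without vehicle 14, and Cldn5 stood at -0.12 without FTY720 6. Pericyte, smooth muscle and meningeal markers had a mean of 0.02 (21 genes, adjusted p = 0.974), with Kcnj8 at -0.17 and Rgs5 at 0.12, and Dcn passed when adjusted over the list alone. Red blood cell genes stood at -0.01 (6 genes, adjusted p = 0.754), with Bpgm at -0.11, Alas2 at 0.15 and Hbb-b2 at -0.15.

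Immune lists did not pass in this lymphocyte-deficient strain. Lymphocyte markers had a mean of 0.02 (21 genes, camera adjusted p = 0.808), and Cd79a, Cd28 and Cd247 had mean levels of 5.19, 3.88 and 4.00 in FTY720 mice, below the median of all genes. Interferon-stimulated genes had a mean of 0.00056 (25 genes, adjusted p = 0.827), with 3 members at an unadjusted p under 0.05 on each side, among them Gbp3 at -0.23, Mx1 at -0.16 and Psmb9 at 0.23. Inflammatory cytokine and NF-kappaB target genes stood at 0.01 (24 genes, adjusted p = 0.974), with Il1a at -0.17, Relb at 0.19 and Nfkb2 at 0.15.

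Cytosolic ribosomal protein genes fell by a mean of 0.04 (49 genes, 41 lower, camera adjusted p = 1.37e-04), with Rpl37 at -0.23 (SE 0.08), Rps20 at -0.10 (SE 0.04) and Rps27l at -0.18 (SE 0.08). With an estimated correlation the adjusted p = 0.872, and with the Gapdh 5' minus 3' difference as a covariate the mean was -0.014 (camera adjusted p = 0.279). Mitochondrial respiratory chain genes had a mean of -0.01 (77 genes, adjusted p = 0.754), with Ndufb10 at -0.12, Cox7a1 at -0.16 and Sdhc at 0.10. Circadian clock genes did not pass (18 genes, mean -0.05, adjusted p = 0.169), with Rora at -0.43 (SE 0.11), Cry1 at -0.29 (SE 0.08) and Dbp at -0.21 (SE 0.08). Their mean ranged from -0.078 without vehicle 15 to -0.015 without vehicle 16. Without vehicle 15 Rora stood at -0.32 and Cry1 at -0.22, and the other probe sets of Rora gave -0.20 each. Cholesterol synthesis genes stood at 0.01 (20 genes, adjusted p = 0.982), with Mvd at -0.14, Fdps at 0.16 and Sc5d at 0.11, and the probe sets of Mvd disagreed in sign. Cholesterol transport genes had a mean of 0.05 (14 genes, adjusted p = 0.220), with Mylip at 0.26 (SE 0.08), Abcg4 at 0.11 and Lipa at 0.08.

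In all, 6 of the 36 lists passed at an adjusted p of 0.05 with the preset correlation, 1 higher and 5 lower, and none passed with an estimated correlation, by fry or by exact permutation. With a smallest p of 0.0286, the permutation test could pass the adjustment only if most lists reached that p, and 1 did. With the preset correlation 12 lists passed without vehicle 15. Of the lists that did not pass with all 8 mice, 8 passed at that correlation in some of the 19 alternative settings. Heat shock did so in 7, circadian, dentate, endothelial, microglia and synaptic plasticity lists in 3 each, and immediate early and interneuron lists in 2 each. In at least 1 of the 8 fits that left out a mouse, the log2 difference of 53 of the 138 named genes and the mean of 31 of the 36 lists was more than 1.5 times smaller or had the other sign. Mean and median had opposite signs in the sphingolipid, core histone, neuropeptide, Ammon's horn, red blood cell, interferon and cholesterol synthesis lists, which did not pass.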

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

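The tests of where vehicle 15 differs were chosen only after its distance from the other arrays was seen. Single mice stood far from the other 3 of their group in 13 of 352 groups of 4 values examined. About 17.6 would do so by chance among independent, unselected values. The genes were partly chosen for small p and groups without overlap, and genes and lists vary together. The count therefore does not show whether single mice are unusual.

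In FTY720 mice, Hbb-b2 was 6.08 in mouse 1 against 5.78 to 5.82 in the others, and Ccn2 was 8.68 in mouse 4 against 8.46 to 8.47. Mouse 5 had the highest Erbin, 9.39 against 9.24 to 9.27, the highest Rps20, 12.46 against 12.40 to 12.41, and the highest mean of the Ammon's horn pyramidal cell markers, 0.04 against -0.02. Mouse 6 had the lowest Lamp5, 9.05 against 9.31 to 9.34, the lowest Olig2, 6.72 against 6.85 to 6.87, and the lowest Pkig, 9.53 against 9.74 to 9.77. In vehicle mice, mouse 16 was high in Fos, 10.12 against 8.62 to 8.86, and in Lamp5, 10.57 against 9.39 to 9.51.

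Vehicle 15 was high in Pcp4, 12.86 against 12.01 to 12.09, and low in Alas2, 5.61 against 5.85 to 5.91, and in Cspg5, 9.24 against 9.55 to 9.58. Over the other 3 vehicle mice its median excess was 1.09 for striatum markers and 1.41 for thalamus markers. The largest excess was that of choroid plexus and ependymal markers, 1.55, with 11 of 15 genes over 1, a list that also varied widely among the other mice. In the same array dentate granule cell markers stood at -0.49 and Ammon's horn markers at -0.11. Lower RNA integrity is argued against, since its Gapdh 5' minus 3' difference of -1.07 lay within the range of the other arrays. The striatum and thalamus excess could come from striatal and thalamic tissue in that dissection, a hypothesis found and tested on the same array. Tac1 stood at 12.52 against a mean of 9.59 and Penk at 11.39 against 9.29. The largest excess of any gene was that of Lhx8, at 6.83 against 3.20. Cartpt stood at 8.76 against 5.97 and Isl1 at 7.76 against 5.06. Lhx8, Cartpt and Isl1 are in neither list, and tissue of further regions was not tested as a source. No biological explanation was tested, because the design gives none for a single vehicle mouse.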

How the results depend on the processing

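No gene passed an adjusted p of 0.05 in the limma fit under any of the alternatives that gave this count, against 823 genes at an unadjusted p under 0.05. The settings without vehicle 15 and 16 and those with a covariate were chosen after the data were seen. The count of 172 genes past unadjusted p 0.01 was 113 among the brighter genes by mean level and 321 with every probe set on its own, where fewer or more features were tested, and 74 with the Gapdh covariate. It ranged from 110 without FTY720 6 to 240 without vehicle 13. The 6 lists became 0 with an estimated correlation, by fry and by exact permutation, whose smallest p of 0.0286 made a pass after adjustment nearly impossible. They ranged from 5 to 12 when 1 mouse was left out (12 without vehicle 15), and under quantile normalization 3 of 7 were higher. The means of the 6 lists stay the same under those 3 tests, -0.30 for myelin, -0.53 for thalamus, -0.042 for ribosomal, -0.52 for striatum, 0.12 for glucocorticoid-responsive and -0.40 for choroid plexus genes. Over all 36 lists the lowest adjusted p was 0.872, 0.226 and 0.823.

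With the preset correlation the myelin list passed in 19 of 19 other settings, from -0.36 to -0.17, and the thalamus list in 19 of 19, from -0.91 to -0.21. Choroid plexus markers passed in 6 of 17. Their mean, without a call, was -0.41 with quantile normalization and with only the dimmest genes removed, -0.40 when centred on bright genes, -0.38 without cross-hybridising probe sets, -0.10 with array weights, -0.35 without vehicle 15 and 16 and -0.25 with the Gapdh covariate. Leaving out 1 mouse gave -0.72 to -0.052. Striatum markers stood at -0.23 with array weights, with no call, and turned to 0.026 without vehicle 15 and 16. With 1 mouse left out they ranged from -0.70 to -0.17. Glucocorticoid-responsive genes ranged from 0.087 to 0.16 with 1 mouse left out, lost the call without FTY720 4, and stood at 0.080, again with no call, without vehicle 15 and 16. Ribosomal genes stood at -0.014 with the Gapdh covariate, with no call. The cause was not tested for any of these.

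A change of sign was counted as a reversal where either value had an unadjusted p under 0.05, a rule set after all sign changes were seen. In all, 29 of 2697 gene values and 72 of 787 list values changed sign, and 12 met the rule. Mvd turned to 0.013 with probe sets averaged and to 0.17 without cross-hybridising probe sets. In the latter setting, where another probe set stands for each of these genes, Fgfr2 turned to 0.031 and Rps20 to 0.082. That probe set was dimmer for Fgfr2, at a mean level of 5.38 against 8.71, and for Rps20, at 5.28 against 12.47. Bdnf turned to -0.20 without vehicle 15 and 16, and pericyte markers to -0.054 there, with a range of -0.040 (without vehicle 15) to 0.064 when 1 mouse was left out. With the Gapdh covariate Krt12 turned to 0.054, immediate early genes to 0.11, endothelial markers to 0.014 and microglia markers to 0.040. The cause was not tested.

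No paired analysis was possible because the groups share no replicate numbers. A pseudocount was not run, as the values were already on the log2 scale, nor was camera with robust variances or the lists with every probe set on its own. Signal over background was not given, which limits what the differences of dim genes show. Such genes include S1pr3, Mx1, Gdnf, Maml2, Il1a, Prox1 and H1f4, with mean levels from 4.72 for S1pr3 down to 2.80 for H1f4.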

Other observations

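The tests with the Gapdh covariate, the additional oligodendrocyte list, the ventral and dorsal genes and the splits for the number of lists were set before their results were seen, while the other tests below were chosen only after the result was seen.

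Some immediate early genes were high in 1 vehicle mouse, vehicle 16, where 5 of the 39 list members stood more than 1 over the other 3 and the median excess was 0.29. Over the mean of the other 3 vehicle mice, vehicle 16 was higher in Egr2 by 2.53, Arc by 1.79, Fos by 1.36, Egr1 by 1.13 and Nr4a1 by 1.01 on the log2 scale, all of them genes that neurons induce within minutes of activity. Its Dusp1 and Junb levels were higher by 0.94 and 0.95. The same mouse had the highest mean of neocortex markers, 0.30, with Lamp5 at 10.57 against a mean of 9.47 in the other 3. Its array had the steepest 5' loss (Gapdh -1.46), and its median excess was -1.23 for choroid plexus and -0.95 for thalamus markers. The genes named here were picked from that mouse after its values were seen.

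Choroid plexus transcripts varied more between mice than between groups. The list mean was 0.77 and 0.55 in FTY720 1 and 5 and -1.03 and -1.09 in FTY720 4 and 6, while in vehicle mice 13 to 16 it was -0.41, 0.72, 1.23 and -0.74. The split that set FTY720 1 and 5 with vehicle 14 and 15 against the rest gave 33 genes at an adjusted p under 0.05, where the treatment gave 0, which points to a structure of the samples apart from treatment. In vehicle 15 the excess over the other vehicle mice was 2.38 for Kcne2, 2.14 for Sostdc1 and 1.99 for Otx2.

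Lower oligodendrocyte and myelin genes in FTY720 mice were weighed against technical sources. Tissue of another region in vehicle 15 is argued against as the whole source, since the list mean was -0.32 without that mouse, and a peculiarity of the list's members is argued against by 26 other oligodendrocyte genes, 23 of them lower, with a mean of -0.15 (exact permutation p = 0.0286, camera p = 6.2e-11 with the preset correlation and p = 0.0655 with an estimated one of 0.38). RNA integrity stays open, because the mean was -0.25 (SE 0.10) without vehicle 16 and -0.17 (SE 0.10) with the Gapdh 5' minus 3' difference as a covariate, and these errors do not settle how much of the shift remains. More white matter in the dissected vehicle tissue may give the same picture, with 20 of 20 members lower, and an effect of FTY720 could as well, with all FTY720 means below all vehicle means by a gap of only 0.021. These cannot be told apart in tissue pieces of unknown cell makeup.

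Among the genes with higher values in FTY720 mice (Dcn, Crym, Npr3, Trpc4, Grp and Ccn3), some are known as ventral hippocampal markers, Dcn and Grp among them, so a larger share of ventral tissue in those samples may be a candidate explanation. Other ventral-enriched minus dorsal-enriched genes differed by 0.53 (SE 0.22, exact permutation p = 0.0571), in the predicted direction but short of the threshold. Among the ventral genes, Rspo2 stood at 0.71 (SE 0.25), Nr2f2 at 0.56 (SE 0.19), Trhr at 0.85 (SE 0.36) and Htr2c at -0.10 (SE 0.22), and of the dorsal ones Spata13 stood at -0.41 (SE 0.16), Wfs1 at -0.03 (SE 0.15) and Tdo2 at 0.07 (SE 0.35). Trhr leaned on vehicle 16, at 5.68 against a mean of 7.10 in the other 3 vehicle mice. The explanation and an effect of FTY720 both stay open.

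All 35 splits of the 8 mice into 4 and 4 were compared with the treatment. For genes past an adjusted p of 0.05, 35 of 35 gave as many as the real 0, which a count of 0 makes certain, so this comparison says nothing about chance, and the highest other number was 33. For genes past unadjusted p 0.01, 3 of 35 splits gave at least the real 172, with 230 as the highest other number, in the split of FTY720 1 and 5 and vehicle 14 and 15 that follows the choroid plexus level, so chance is not excluded, and with the choroid plexus list mean as a covariate the real count was 160. For lists past the threshold, 24 of 35 gave at least the real 6, with 13 as the highest other number, so chance is not excluded. For the size of the myelin shift, only the real split, 1 of 35, reached 0.297, with 0.286 as the highest other value, and 1 is the fewest splits possible. The list was singled out of 36 after its result was seen, and its exact permutation p adjusted over the lists was 0.823, so chance is not excluded.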
